A study of Arabidopsis thaliana with 30 samples.

How the data were processed

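Transcripts were measured in whole leaves of Arabidopsis jazD plants, 26 days old, grown at 20 °C under 16 h of light at 100 µE and 8 h of darkness, the first 7 days under a dome. Plants were sprayed with 5 µM coronatine in water or with water, and 3 replicates per treatment were taken at 0, 1, 3, 12 and 24 h. Per the labels' protocols, total RNA was purified with the NucleoSpin plant kit with DNase on the column, samples had an RNA integrity number of at least 6.5, and libraries made with a BGI transcriptome kit were sequenced on a DNBseq instrument. Samples were grouped by the treatment and time in their titles.

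The authors deposited gene-level expression as TPM for 27655 genes and 30 samples, each column summing to between 999999 and 1000001. Per the submitters' processing notes, the tools were RSEM 1.3.3 and DESeq2 and the build was TAIR10. The notes do not say what each tool was used for. The aligner settings, the annotation release and any strand setting were not given in the sources used here. TPM divides by transcript length and by the total of each sample, so it keeps no depth, and no interval from counting error could be given. Per the file headers, the authors also deposited a table per time comparing coronatine with mock leaves, with a base mean (a normalized signal per gene), a log2 fold change and its standard error on the log2 scale, and a p-value with its adjusted form. Those tables list 33323 loci, 21768 with values. They were used as an alternative to the test here and as the source of coordinates, which are on TAIR10 and cover whole genes. Symbols were those of the gene lists described below or else of a RefSeq gene table, in which 27445 of the 27655 loci had a match. Coordinates were not taken from the reference genome.

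Genes with a TPM of at least 1 in at least 3 samples were tested, 19005 genes or 68.7% of the table. Values were taken as log2(TPM + 1), so that log2 differences understate the change of low genes. A mean per treatment and time was fitted over all 30 samples with limma 3.58.1 in R 4.3.3, with a mean-variance trend. Tests were two-sided, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. The comparisons were coronatine against mock at each time, the difference of that effect between 2 times, and mock leaves against mock leaves at 0 h. Overlap between times was tested with Fisher's exact test with 95% confidence intervals.

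The planned tests were fixed before the data were examined. Because the median gene shifted on the TPM scale, TPM was also rescaled with TMM factors, computed with a trim of 30% on log ratios and 5% on mean log values. The rule that a gene rose or fell only if called alike on both scalings was chosen after seeing the data, as were the alternatives for mock leaves over time and for the overlaps, and the use of an estimated correlation on TMM-rescaled TPM.

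Before the data were examined, 32 lists with 451 genes were fixed: the 13 JAZ repressors, jasmonate synthesis, turnover, signalling regulators and defence markers, indole and aliphatic glucosinolate and anthocyanin synthesis, chlorophyll breakdown and synthesis, light-harvesting complex, nuclear photosystem, Calvin cycle, plastid-encoded and plastid ribosome genes, chloroplast regulators, senescence, autophagy, proteases, cell cycle, salicylate, abscisic acid, endoplasmic reticulum stress, clock and touch genes, and markers of guard cells, phloem, xylem, epidermis, trichomes, myrosin cells and flowers. The filter removed 14 members: DAD1, MYC5, BHLH14, accD, ALPHA-VPE, CEP1, RD29B, NAC103, VND7, AP1, AP3, PI, AG and SEP3. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over 155 pairs of list and time, and again with an estimated correlation.

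Genes named at each time were the 10 with the largest positive and the 10 with the largest negative log2 difference among those past the threshold, with a mean TPM of at least 10 in the higher group, all 3 coronatine values beyond all 3 mock values, and a symbol. For differences between times the rule took 5 each way, with the values compared at the later time. From each list up to 3 members each way and 1 or 2 not past the threshold could be named, and a fixed set that includes the JAZ genes could be named at any time.

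The procedure was tested on simulated data before use. In the 0 h comparison, with 19005 genes, simulated log2 changes of 0.5 were recovered in 68% of 50 genes, changes of 1 in 98% and changes of 2 and 3 in 100%, and 9 of 192 calls (4.7%) were false. The simulation moved a small part of the genes, in random directions and without a shift of the median gene. It therefore gives no share of false calls for the later times, where most genes were called and the median shifted. Alternatives were pseudocounts of 0.1 and 5, no filter or a TPM of at least 5, quantile normalization, TMM factors, removal of the 210 plastid and mitochondrial loci, a fit without the trend, sample weights, the replicate number as a block, the label number as a correlated unit, a fit on the 2 groups alone, a log2 difference of at least 1, and leaving out each sample. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No 2 TPM columns were identical.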

Results

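Whole leaves of Arabidopsis thaliana carrying jazD were profiled by RNA sequencing during a 24 h response to coronatine, a bacterial mimic of the hormone conjugate jasmonoyl-isoleucine. The labels give the genotype only as jazD, in the Col-0 ecotype. From general knowledge of the line, and not from the labels, jazD carries disruptions in 10 of the 13 JAZ genes, which encode repressors of jasmonate signalling, and JAZ8, JAZ11 and JAZ12 are taken here as intact. Plants were 26 days old when they were sprayed with 5 µM coronatine in water or with water alone (mock), and leaves were harvested at 0, 1, 3, 12 and 24 h. The 30 libraries formed 10 groups of 3 replicates. Values were length-normalised transcript abundances (TPM), which keep no record of sequencing depth. The depth of each library is therefore unknown. Replicates of a group were close to one another, with Spearman correlations from 0.986 to 0.995 across genes. The first principal component of the log2 values carried 71.0% of the variance, the second 12.0% and the third 5.9%. No label states that the replicates came from separate plants. The p-values therefore measure the spread between these libraries, which may be technical. Per its design text, the series addressed the transcriptome of jazD leaves during degreening by coronatine. No measure of chlorophyll or leaf colour was analysed here. Treated leaves were compared with mock leaves at each time.

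The JAZ genes were examined first because the line is defined by them. Reads from a disrupted locus may be partial, so a TPM value there does not show an intact transcript. No wild-type library was analysed here. Which loci are disrupted was not tested in these data. Among the 10 loci taken as disrupted the highest single-library values were 978 TPM for JAZ10 and 924 TPM for JAZ9. JAZ2 ranged from 1.98 to 5.44 TPM and JAZ4 reached 7.46 TPM. Of the 3 loci taken as intact, JAZ8 (AT1G30135, chromosome 1, 10596492 to 10597239, forward strand, TAIR10) ranged from 11.3 to 763 TPM, JAZ11 (AT3G43440) from 9.90 to 111 TPM and JAZ12 (AT5G20900) from 82.6 to 232 TPM. In mock leaves at 0 h, JAZ8 stood at 24.3 ± 2.35 TPM, JAZ11 at 10.8 ± 0.909 TPM and JAZ12 at 108 ± 3.44 TPM (mean ± SD, n = 3, as for every group below).

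At 0 h, no single gene separated treated from mock leaves past the threshold. Of 19005 genes tested, 0 passed the limma threshold, 1012 had an unadjusted p under 0.05 and the smallest adjusted p was 0.068. The authors' deposited table for 0 h also held 0 genes at an adjusted p under 0.05, with 786 at an unadjusted p under 0.05. LOX2 (AT3G45140), a lipoxygenase of jasmonate synthesis, read 3084 ± 176 against 3759 ± 269.5 TPM, and RBCS1A (AT1G67090), which encodes a Rubisco small subunit, read 18954 ± 243 against 19861 ± 524 TPM. Camera nevertheless called 16 of the 31 gene lists at 0 h, each with a median within 0.25 log2 units of all genes. With an estimated correlation only the indole glucosinolate list remained called (adjusted p = 0.046). Several of these calls rested on 1 library. Without coronatine 0 h replicate 3 camera no longer called JAZ repressors (adjusted p = 0.080) or jasmonate turnover (adjusted p = 0.18). Without mock 0 h replicate 3 it lost both (adjusted p = 0.063 and 0.14), jasmonate synthesis (adjusted p = 0.11) and guard cell markers (adjusted p = 0.11). Camera lost anthocyanin synthesis (adjusted p = 0.38 and 0.83) and the senescence list (adjusted p = 0.17 and 0.34) without coronatine 0 h replicate 1 or mock 0 h replicate 1. Without mock 0 h replicate 1 it also lost autophagy (adjusted p = 0.17) and cell cycle (adjusted p = 0.17). Cell cycle (camera adjusted p = 0.14) and guard cell markers (camera adjusted p = 0.063) were lost without coronatine 0 h replicate 2, and epidermis markers (camera adjusted p = 0.075) without mock 0 h replicate 2. The xylem call was lost without any 1 library other than coronatine 0 h replicate 1 (camera adjusted p from 0.052 to 0.21). Camera called 4 further lists only without 1 library: defence markers, salicylate response, phloem and trichome markers (lowest adjusted p 6.2e-04, 4.3e-04, 0.042 and 0.028). Camera calls at later times were therefore read beside the counts of members that changed.

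From 1 h on, the TPM of the median gene was lower in coronatine leaves than in mock leaves, by −0.18 at 1 h, −0.46 at 3 h, −0.54 at 12 h and −0.24 at 24 h on the log2 scale, against 0.02 at 0 h. Single genes are said to have risen or fallen only where limma called them in the same direction on TPM as deposited and on TPM rescaled with trimmed-mean (TMM) factors. At 1, 3, 12 and 24 h every gene called lower after TMM rescaling was also called lower on TPM as deposited. From 3 h on every gene called higher on TPM as deposited was also called higher after TMM rescaling, as were 1809 of 1814 at 1 h. Rises were thus set by the TPM calls and falls by the TMM calls, so the balance between them depends on the rule. List medians are given relative to the median of all tested genes. Camera was run at a preset correlation, and from 1 h on, where no p with an estimated correlation follows a called list, the call held with one on TPM as deposited. On TMM-rescaled TPM with an estimated correlation camera called 0 lists at each time, with 3, 6, 6, 7 and 3 lists at an unadjusted p under 0.05 at 0, 1, 3, 12 and 24 h. Over the 155 pairs of list and time, the count of members adjusted over the list alone equalled that over all genes in 142 and differed by at most 4 members. Of all tested genes, 25.0, 50.2, 65.9 and 80.8% rose or fell at 1, 3, 12 and 24 h. The count of list members that rose or fell is to be read against these shares, which many lists do not clearly exceed. A count of risers alone, or of falls alone, is to be read against the genes that changed in that direction. Of the 19005 genes, 1809, 2693, 4609 and 7079 rose at these times, and 2942, 6848, 7924 and 8271 fell. Log2 differences are on the log2(TPM + 1) scale and understate the change of low genes.

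At 1 h, most genes of the jasmonate pathway and of indole glucosinolate synthesis rose. BSMT1 (AT3G11480), a methyltransferase that makes methyl salicylate, rose to 291 ± 32.9 against 7.45 ± 5.30 TPM. JAZ8 rose to 699.6 ± 55.5 against 24.1 ± 8.85 TPM, a log2 difference of 4.86 ± 0.16 (limma adjusted p = 6.1e-18). The protein kinase genes MAPKKK21 (AT4G36950, 134 ± 9.50 against 3.38 ± 3.31 TPM) and MAPKKK19 (AT5G67080, 132 ± 13.9 against 3.34 ± 0.757 TPM) rose as well. So did the transcription factor genes MYB24 (AT5G40350, 52.0 ± 4.51 against 1.13 ± 0.588 TPM), RAP2.6 (AT1G43160, 112 ± 8.84 against 5.22 ± 5.24 TPM) and RRTF1 (AT4G34410, 25.5 ± 1.90 against 0.653 ± 0.595 TPM). CYP82G1 (AT3G25180), which makes a volatile homoterpene, reached 47.3 ± 7.04 against 2.78 ± 2.75 TPM, and TRFL4 (AT3G53790) reached 25.1 ± 6.04 against 0.173 ± 0.214 TPM. Under the naming rule the largest falls were in COL2 (AT3G02380, 5.95 ± 0.915 against 30.4 ± 3.47 TPM) and the growth regulator HBI1 (AT2G18300, 19.3 ± 1.99 against 86.5 ± 1.55 TPM). The B-box gene BBX14 (AT1G68520) read 14.0 ± 0.911 against 58.2 ± 1.32 TPM and EPR1 (AT1G18330) 2.94 ± 0.530 against 14.4 ± 0.280 TPM. RTFL16 (AT3G25717), ATCTH (AT2G25900), CIA2 (AT5G57180), BAM2 (AT3G49670) and LTP2 (AT2G38530) completed the 10 largest falls together with GNC (AT5G56860).

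By gene group at 1 h, 10 of 13 JAZ genes rose and 0 fell, with a relative median of 1.26 (camera adjusted p = 1.3e-13). JAZ2 (2.93 ± 0.474 against 2.96 ± 0.313 TPM), JAZ4 (0.170 ± 0.106 against 0.280 ± 0.157 TPM) and JAZ11 (10.2 ± 0.349 against 11.2 ± 0.315 TPM) did not pass. All 10 jasmonate turnover genes rose (camera adjusted p = 8.4e-16). They included the jasmonate oxidase JOX4 (AT2G38240, 421 ± 38.3 against 19.5 ± 18.7 TPM) and the cytochrome P450 genes CYP94C1 (AT2G27690, 293 ± 25.9 against 24.7 ± 22.4 TPM) and CYP94B1 (AT5G63450, 50.8 ± 2.05 against 4.00 ± 4.70 TPM). The mock SDs of these genes, and of MAPKKK21, RAP2.6, RRTF1 and CYP82G1 above, were near or above their means. In each of them 1 library carried most of the mock mean. Their limma calls held without any 1 library. Of 17 synthesis genes 12 rose and 0 fell (camera adjusted p = 1.8e-15). Among them were the lipoxygenases LOX3 (AT1G17420, 446 ± 32.3 against 39.4 ± 23.8 TPM) and LOX4 (AT1G72520, 430.2 ± 35.8 against 37.5 ± 10.4 TPM). Signalling regulators split, 9 of 15 rising and 3 falling (camera adjusted p = 1.4e-09). MYC2 (AT1G32640), the central activator, rose to 240.1 ± 2.11 against 68.2 ± 10.3 TPM, and COI1 (AT2G39940), the receptor subunit, fell to 9.30 ± 0.951 against 14.5 ± 0.335 TPM. Indole glucosinolate genes rose in 13 of 17 members (camera adjusted p = 2.2e-15), with the activator MYB34 (AT5G60890) at 105 ± 18.7 against 24.0 ± 8.72 TPM. Defence markers rose in 7 of 14 (camera adjusted p = 1.7e-06, adjusted p = 0.22 with an estimated correlation). Among them were the terpene synthase TPS04 (AT1G61120), at 239 ± 32 against 24.7 ± 9.84 TPM, and the tyrosine aminotransferase TAT3 (AT2G24850), at 562 ± 137 against 67.9 ± 18.7 TPM. VSP1 (AT5G24780), a vegetative storage protein gene, rose to 1525 ± 128 against 1011 ± 242 TPM (limma adjusted p = 0.039). The VSP1 call was lost with no filter (limma adjusted p = 0.057), after quantile normalization (limma adjusted p = 0.15) and without any 1 of the 6 libraries other than mock 1 h replicate 2 (limma adjusted p from 0.051 to 0.16). The defensin gene PDF1.2 (AT5G44420) read 14947 ± 2256 against 13665 ± 2094 TPM and did not pass.

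Chloroplast regulators and a few pigment genes also moved at 1 h. Of 11 chloroplast transcription regulators 7 fell and 0 rose (camera adjusted p = 0.0019, adjusted p = 0.29 with an estimated correlation). GLK2 (AT5G44190) fell to 58.2 ± 2.91 against 139.5 ± 8.41 TPM and the GATA factor CGA1 (AT4G26150) to 0.95 ± 0.181 against 5.43 ± 1.18 TPM, while GLK1 (AT2G20570) read 239 ± 22.5 against 250.1 ± 12.9 TPM and did not pass. In the chlorophyll breakdown list 4 of 14 rose and 1 fell (camera adjusted p = 0.043, adjusted p = 0.27 with an estimated correlation). That camera call was not kept without coronatine 1 h replicate 1 (adjusted p = 0.075). The chlorophyllase CLH1 (AT1G19670) reached 3683 ± 148 against 1442 ± 89.8 TPM and the pheophytinase PPH (AT5G13800, chromosome 5, 4451837 to 4454576, reverse strand) reached 118 ± 4.15 against 60.4 ± 3.96 TPM. SGR1 (AT4G22920), which encodes the magnesium dechelatase of chlorophyll a, read 17.4 ± 1.99 against 21.4 ± 1.16 TPM. Limma called it lower on TPM as deposited (adjusted p = 0.024) and not after TMM rescaling (adjusted p = 0.53). On TPM as deposited the SGR1 call was also lost without coronatine 1 h replicate 3 (limma adjusted p = 0.14) or mock 1 h replicate 2 (limma adjusted p = 0.092), and it was lost after quantile normalization (limma adjusted p = 0.20) and in the authors' deposited table (adjusted p = 0.56). Of 24 chlorophyll synthesis genes 3 fell, with PORB (AT4G27440), a protochlorophyllide reductase, at 216 ± 19.3 against 467 ± 23.6 TPM. That list was not called (camera adjusted p = 0.081) over all libraries. Camera called it without coronatine 1 h replicate 2 (adjusted p = 0.025) or mock 1 h replicate 3 (adjusted p = 0.047). The light-harvesting list had 1 riser, LHCB7 (AT1G76570, 27.3 ± 1.32 against 12.5 ± 0.348 TPM), and 0 that fell (camera adjusted p = 0.64). Epidermis markers fell in 4 of 6 (camera adjusted p = 0.25), beside the falls in the chloroplast regulators. Camera called the senescence (6 rose, 2 fell of 22), salicylate (4 rose of 15) and abscisic acid lists (3 rose of 11) higher (adjusted p = 0.0030, 7.2e-04 and 0.018). Cell cycle was called lower, with 8 of 20 falling (camera adjusted p = 0.033), but not without coronatine 1 h replicate 1 (0.22) or mock 1 h replicate 2 (0.0605). None held with an estimated correlation (camera adjusted p = 0.46, 0.48, 0.30 and 0.70).

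In all, limma called 9733 of 19005 genes at 1 h on TPM as deposited, 1814 higher and 7919 lower. After TMM rescaling it called 6132, 3190 higher and 2942 lower. Quantile normalization gave 2549 higher and 4210 lower, and the authors' deposited table listed 3109 higher and 2910 lower. Calls held on both TPM scalings for 1809 genes higher and 2942 lower.

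**Figure D1:**
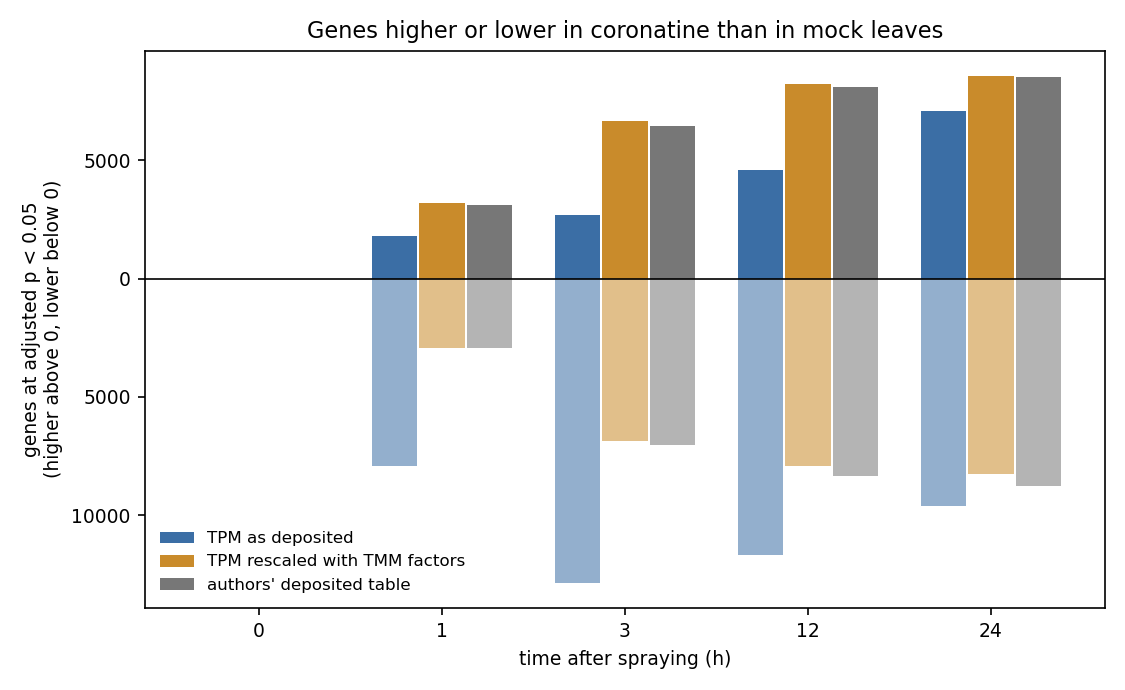
Number of genes at an adjusted p under 0.05 that were higher (above 0) or lower (below 0) in coronatine than in mock leaves at each time in h. The bars of limma on TPM as deposited, limma on TMM-rescaled TPM and the authors' deposited table stand at 2693, 6682 and 6453 genes higher at 3 h, and at 0 genes at 0 h.

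At 3 h, most genes of jasmonate turnover, of both kinds of glucosinolate synthesis and of anthocyanin synthesis rose, and most epidermis markers and chloroplast regulators fell. BSMT1 rose to 1946 ± 145 against 4.70 ± 2.49 TPM, JOX4 to 2121 ± 141 against 12.0 ± 3.79 TPM and CYP94B1 to 467 ± 56.0 against 1.81 ± 0.720 TPM. ILL5 (AT1G51780) reached 345 ± 19.0 against 0.723 ± 0.732 TPM and the terpene synthase TPS10 (AT2G24210) 619 ± 31.5 against 2.22 ± 0.926 TPM. TPS02 (AT4G16730) stood at 244 ± 14.8 against 0.830 ± 0.513 TPM and the jasmonate methyltransferase JMT (AT1G19640) at 685 ± 34.2 against 4.07 ± 0.436 TPM. CYP71B37 (AT3G26330), NAC025 (AT1G61110) and the glutathione transferase GSTU6 (AT2G29440) were the others of the 10 largest rises. Among the falls, ACD6 (AT4G14400), an ankyrin gene of salicylate-linked defence, read 3.60 ± 1.59 against 159 ± 15.5 TPM and the expansin EXPA8 (AT2G40610) 2.86 ± 1.02 against 93.0 ± 12.5 TPM. GASA6 (AT1G74670) fell to 2.01 ± 0.702 against 80.02 ± 4.26 TPM, the ferric reductase FRO6 (AT5G49730) to 5.13 ± 0.727 against 139.7 ± 6.01 TPM and the auxin carrier PIN7 (AT1G23080) to 1.89 ± 0.286 against 48.6 ± 1.76 TPM. The other 5 were KCS12 (AT2G28630), HIPL2 (AT5G62630), TCL2 (AT2G30424), CNGC11 (AT2G46440) and FRO7 (AT5G49740).

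By gene group at 3 h, JAZ genes rose in 10 of 13 (camera adjusted p = 3.1e-11). Turnover genes rose in 10 of 10, with a relative median of 5.23 (camera adjusted p = 1.2e-13). Synthesis genes rose in 13 of 17 with 1 falling (camera adjusted p = 7.2e-11, adjusted p = 0.052 with an estimated correlation). The allene oxide synthase gene AOS (AT5G42650) reached 4386 ± 362 against 496 ± 24.2 TPM and LOX2 9777 ± 560.1 against 1767 ± 76.2 TPM. Regulators rose in 10 and fell in 4 of 15 (camera adjusted p = 1.0e-06). NAC019 (AT1G52890) rose to 270.3 ± 26.5 against 6.83 ± 1.79 TPM, and ORA59 (AT1G06160), an ethylene-response factor that activates defensin genes, fell to 52.2 ± 2.11 against 137 ± 6.68 TPM. Defence markers rose in 8 of 14 (camera adjusted p = 3.2e-07, adjusted p = 0.19 with an estimated correlation). TPS04 stood at 1432 ± 105 against 12.9 ± 4.58 TPM and VSP1 at 5515 ± 348 against 718 ± 113 TPM. PDF1.2 read 18247 ± 3032 against 17742 ± 1625 TPM. Limma did not call this difference on TPM as deposited (adjusted p = 0.91) and called higher after TMM rescaling (adjusted p = 0.032). Indole glucosinolate genes rose in 13 and fell in 2 of 17 (camera adjusted p = 2.9e-12). CYP79B3 (AT2G22330) reached 1162 ± 58.8 against 79.99 ± 6.53 TPM, and the regulator MYB51 (AT1G18570) fell to 3.73 ± 0.954 against 39.3 ± 4.77 TPM. Aliphatic glucosinolate genes rose in 13 and fell in 1 of 16, with a relative median of 1.81 (camera adjusted p = 8.5e-09, adjusted p = 0.24 with an estimated correlation). At 1 h 6 had risen and 1 had fallen (camera adjusted p = 3.5e-04, adjusted p = 0.46 with an estimated correlation). FMOGS-OX1 (AT1G65860), a side-chain oxygenase, rose to 118 ± 9.72 against 14.0 ± 1.5 TPM at 3 h, and MYB28 (AT5G61420), the activator of the pathway, fell to 11.8 ± 1.34 against 39.4 ± 6.84 TPM. Of 16 anthocyanin genes 2 had risen and 6 had fallen at 1 h (camera adjusted p = 0.53). At 3 h 10 of them rose and 1 fell (camera adjusted p = 1.8e-06, adjusted p = 0.36 with an estimated correlation). Chalcone synthase, CHS (AT5G13930), rose to 747 ± 24.0 against 141 ± 29.2 TPM.

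At 3 h, 5 chlorophyll breakdown genes rose and 11 chlorophyll synthesis genes fell, while the calls of photosystem and plastid ribosome genes changed direction with the scaling. PPH reached 346 ± 19.7 against 54.5 ± 2.79 TPM and CLH1 5216 ± 179 against 864 ± 36.5 TPM. PAO (AT3G44880), pheophorbide a oxygenase, reached 161 ± 10 against 66.2 ± 0.376 TPM. SGR1 read 13.8 ± 1.66 against 16.2 ± 2.25 TPM and did not pass on TPM as deposited (limma log2 difference −0.22 ± 0.10, adjusted p = 0.057). Its sign turned with the scaling, to 0.31 after TMM rescaling (limma adjusted p = 0.011), 0.23 after quantile normalization and 0.31 in the authors' deposited table. On TPM as deposited, limma called it lower without coronatine 3 h replicate 1 (adjusted p = 0.017), mock 3 h replicate 2 (adjusted p = 0.042) or mock 3 h replicate 3 (adjusted p = 0.033). The chlorophyll breakdown list had 5 of 14 members that rose and 0 that fell (camera adjusted p = 0.035, adjusted p = 0.24 with an estimated correlation). Of 24 chlorophyll synthesis genes 11 fell and 1 rose (camera adjusted p = 0.075). CHLH (AT5G13630), a magnesium chelatase subunit, fell to 257 ± 28.3 against 513 ± 22.7 TPM. Without mock 3 h replicate 1 camera called that list (adjusted p = 0.043). Chloroplast regulators fell in 10 of 11 (camera adjusted p = 0.0083, adjusted p = 0.36 with an estimated correlation). In the nuclear photosystem list 2 higher and 23 lower were called on TPM as deposited and 13 higher and 0 lower after TMM rescaling. By the joint rule 2 of 30 rose and 0 fell (camera adjusted p = 0.92). The nuclear plastid ribosome genes likewise had 0 higher and 25 lower on TPM and 21 higher and 0 lower after TMM rescaling (camera adjusted p = 0.67). RBCS1A read 16297 ± 1874 against 16821 ± 985 TPM. Limma did not call it on TPM as deposited (adjusted p = 0.71) and called higher after TMM rescaling (adjusted p = 4.4e-04). Epidermis markers fell in 5 of 6 with 1 rising, with FDH (AT2G26250) at 25.9 ± 0.795 against 128 ± 16.9 TPM (camera adjusted p = 0.27). The senescence list split, 8 of 22 rising and 7 falling (camera adjusted p = 0.026, adjusted p = 0.58 with an estimated correlation). CLPD (AT5G51070) rose to 869 ± 41.6 against 107 ± 6.81 TPM, and NAP (AT1G69490), a NAC factor of leaf senescence, fell to 1.39 ± 0.329 against 11.3 ± 1.52 TPM.

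At 3 h limma called 15536 genes on TPM as deposited, 2693 higher and 12843 lower. After TMM rescaling it called 13530, 6682 higher and 6848 lower. Quantile normalization gave 5794 higher and 7810 lower, and the authors' deposited table listed 6453 higher and 7029 lower. On both TPM scalings 2693 genes were higher and 6848 lower, and 1798 were called in opposite directions by the scalings.

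At 12 h, most chlorophyll breakdown genes had risen and most genes of the photosynthetic apparatus had fallen. TPS10 (AT2G24210) reached 4132 ± 155 against 7.83 ± 5.68 TPM and the methionine sulfoxide reductase MSRB7 (AT4G21830) 6043 ± 572 against 23.0 ± 5.94 TPM. BSMT1 reached 8808 ± 323 against 46.4 ± 23.3 TPM and GSTU6 1291 ± 161 against 4.19 ± 1.74 TPM. HSP17.6II (AT5G12020) stood at 238 ± 8.43 against 0.457 ± 0.250 TPM and the polygalacturonase PGAZAT (AT2G41850) at 253 ± 57.8 against 0.427 ± 0.523 TPM. ILL5, NAC025, ELI3-2 (AT4G37990) and TRFL4 completed the 10 largest rises. ACD6 fell to 5.61 ± 7.95 against 489.6 ± 21.8 TPM, AACT1 (AT5G61160) to 4.38 ± 5.35 against 360.3 ± 68.3 TPM and the thiamine synthesis gene THI1 (AT5G54770) to 75.0 ± 14.9 against 3786 ± 7.65 TPM. For ACD6 and AACT1 the coronatine SD exceeded the mean, most of which 1 library carried, and both limma calls held without any 1 library. The germin-like GER3 (AT5G20630) fell to 20.9 ± 6.14 against 1439.6 ± 154 TPM and the carbonic anhydrase CA2 (AT5G14740) to 28.8 ± 6.91 against 1451 ± 46.4 TPM. ORA59 (chromosome 1, 1883004 to 1883934, forward strand) fell to 1.33 ± 1.12 against 81.7 ± 10.6 TPM. LTL1 (AT3G04290), the aldolase FBA5 (AT4G26530), IGMT4 (AT1G21130) and PME44 (AT4G33220) were the other falls among the 10 largest.

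The chlorophyll breakdown list at 12 h had 8 members that rose and 3 that fell of 14 (camera adjusted p = 0.0027, adjusted p = 0.086 with an estimated correlation). SGR1 stood at 177 ± 19.7 against 18.8 ± 2.18 TPM and PAO at 732 ± 4.29 against 73.9 ± 6.35 TPM. PPH stood at 818 ± 12.3 against 79.0 ± 13.1 TPM and CYP89A9 (AT3G03470), which acts on chlorophyll catabolites, at 259 ± 18.5 against 11.7 ± 0.193 TPM. Of the chlorophyll synthesis genes 21 of 24 fell and 2 rose (camera adjusted p = 1.2e-04, adjusted p = 0.46 with an estimated correlation). PORB read 15.5 ± 2.25 against 459 ± 16.4 TPM, CHLH 41.3 ± 5.81 against 199 ± 2.74 TPM and the methyltransferase CHLM (AT4G25080) 18.4 ± 2.34 against 216 ± 6.86 TPM. All 27 nuclear plastid ribosome genes fell (camera adjusted p = 6.6e-07, adjusted p = 0.44 with an estimated correlation). So did 19 of 20 Calvin cycle genes (camera adjusted p = 2.5e-05, adjusted p = 0.46 with an estimated correlation). Photosystem genes fell in 20 of 30, with 1 rising (camera adjusted p = 9.3e-04, adjusted p = 0.68 with an estimated correlation). Light-harvesting genes fell in 14 of 21, with 1 rising (camera adjusted p = 0.034, adjusted p = 0.76 with an estimated correlation). RBCS1A read 5636 ± 747 against 18960.0 ± 429 TPM and Rubisco activase, RCA (AT2G39730), 439 ± 49.0 against 3692 ± 64.0 TPM. Members of the RBCS, LHCB1, LHCB2 and PDF1.2 families are near-identical, so the division of reads among them is uncertain. Chloroplast regulators fell in 9 and rose in 2 of 11 (camera adjusted p = 0.088). GLK2 fell to 2.79 ± 0.705 against 41.4 ± 2.27 TPM. All 6 epidermis markers fell beside these lists (camera adjusted p = 0.028, adjusted p = 0.44 with an estimated correlation). All 20 cell cycle genes fell too (camera adjusted p = 0.0040, adjusted p = 0.58 with an estimated correlation). PCNA1 (AT1G07370), a DNA replication clamp, stood at 3.02 ± 0.696 against 20.1 ± 0.848 TPM.

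Jasmonate and autophagy genes rose at 12 h. JAZ genes rose in 12 of 13 (camera adjusted p = 2.9e-08, adjusted p = 0.051 with an estimated correlation). Turnover genes rose in 10 of 10 (camera adjusted p = 3.7e-08, adjusted p = 0.15 with an estimated correlation). Synthesis genes rose in 14 of 17 (camera adjusted p = 1.2e-07, adjusted p = 0.13 with an estimated correlation) and signalling regulators in 11 of 15 with 1 falling (camera adjusted p = 1.2e-04, adjusted p = 0.086 with an estimated correlation). Defence markers divided, 8 rising and 3 falling of 14 (camera adjusted p = 0.0051, adjusted p = 0.46 with an estimated correlation). VSP1 stood at 17551 ± 676 against 1202 ± 364 TPM and HEL (AT3G04720) at 687 ± 101 against 2881 ± 424 TPM. PDF1.2 read 9478 ± 1139 against 18538 ± 3221 TPM. Limma called this difference on TPM as deposited (adjusted p = 7.1e-04) and not after TMM rescaling (adjusted p = 0.33). Indole glucosinolate genes rose in 12 of 17 with 2 falling (camera adjusted p = 1.4e-04, adjusted p = 0.29 with an estimated correlation). Aliphatic ones fell in 11 of 16 and rose in 3 (camera adjusted p = 0.65). Autophagy genes rose in 25 of 34 and fell in 1 (camera adjusted p = 1.7e-08, adjusted p = 0.22 with an estimated correlation). ATG8H (AT3G06420) reached 118 ± 12.4 against 12.2 ± 2.26 TPM. In the senescence list 12 of 22 rose and 3 fell (camera adjusted p = 3.7e-04, adjusted p = 0.37 with an estimated correlation). The NAC factor ORE1 (AT5G39610) reached 49.7 ± 5.60 against 1.86 ± 0.150 TPM, while SAG12 (AT5G45890), a senescence protease, read 0.247 ± 0.214 against 0.117 ± 0.126 TPM and did not pass. In the abscisic acid and dehydration list 6 of 11 genes had risen and 2 had fallen at 3 h (camera adjusted p = 7.4e-04, adjusted p = 0.13 with an estimated correlation). At 12 h 7 of 11 rose (camera adjusted p = 2.2e-04, adjusted p = 0.089 with an estimated correlation). NCED3 (AT3G14440), an enzyme of abscisic acid synthesis, stood at 31.9 ± 2.65 against 1.15 ± 0.217 TPM.

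At 12 h limma called 16309 genes on TPM as deposited, 4609 higher and 11700 lower. After TMM rescaling it called 16164, 8240 higher and 7924 lower. Quantile normalization gave 7631 higher and 8157 lower, and the authors' deposited table listed 8114 higher and 8353 lower. On both TPM scalings 4609 genes were higher and 7924 lower, and 1547 were called in opposite directions.

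At 24 h nearly all listed nuclear photosynthesis genes fell and most senescence, autophagy and chlorophyll breakdown genes rose. The 10 largest rises under the naming rule included TPS10 (AT2G24210, 5397 ± 89.9 against 1.08 ± 0.441 TPM), MSRB7 (7131 ± 93.3 against 5.58 ± 0.343 TPM) and BSMT1 (12195 ± 615 against 14.9 ± 2.94 TPM). The β-glucosidase BGLU22 (AT1G66280) reached 1561 ± 110.1 against 1.1 ± 0.564 TPM, the glycosyl hydrolase GH9B15 (AT4G23560) 909.6 ± 70.5 against 0.123 ± 0.0351 TPM and PGAZAT 819 ± 146 against 0.0933 ± 0.0681 TPM. DXPS1 (AT3G21500), TPS03 (AT4G16740), NAC025 and ELI3-2 completed these rises. The largest falls included LHCB2.3 (AT3G27690, 6.20 ± 1.98 against 2395 ± 111 TPM), RBCS2B (AT5G38420, 31.2 ± 2.77 against 6725 ± 414 TPM) and LHCB1.4 (AT2G34430, 18.8 ± 1.75 against 3662 ± 133 TPM). CA2 fell to 9.04 ± 0.757 against 1752 ± 58.6 TPM and FBA5 to 0.233 ± 0.275 against 306 ± 5.65 TPM, beside AACT1 (AT5G61160), LTL1, OEP6 (AT3G63160), PCC1 (AT3G22231) and GER3.

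All 20 Calvin cycle genes fell at 24 h, with a relative median of −3.16 (camera adjusted p = 1.1e-07, adjusted p = 0.36 with an estimated correlation). So did all 30 photosystem genes (camera adjusted p = 4.9e-09, adjusted p = 0.42 with an estimated correlation) and all 27 plastid ribosome genes (camera adjusted p = 3.5e-10, adjusted p = 0.34 with an estimated correlation). Of 21 light-harvesting genes 20 fell (camera adjusted p = 2.8e-06, adjusted p = 0.44 with an estimated correlation), LHCB7 rising instead. RBCS1A (chromosome 1, 25048158 to 25049424, reverse strand) fell to 1796 ± 326 against 21028 ± 757 TPM, a log2 difference of −3.56 ± 0.12 (limma adjusted p = 2.2e-19). RCA fell to 709 ± 107 against 7122 ± 149 TPM. Chlorophyll synthesis genes fell in 23 of 24 (camera adjusted p = 7.9e-08, adjusted p = 0.34 with an estimated correlation). PORB stood at 2.27 ± 0.199 against 246 ± 11.1 TPM and CHLH at 118 ± 22.9 against 865 ± 17.4 TPM. Chlorophyll breakdown genes rose in 11 and fell in 3 of 14 (camera adjusted p = 0.0024, adjusted p = 0.086 with an estimated correlation). SGR1 reached 351 ± 15.5 against 23.3 ± 1.62 TPM and the chlorophyll b reductase NYC1 (AT4G13250) 319 ± 47.5 against 35.1 ± 1.80 TPM. PPH reached 571 ± 7.34 against 48.6 ± 2.35 TPM and PAO 749 ± 23.7 against 59.5 ± 1.97 TPM. Chloroplast regulators fell in 9 and rose in 2 of 11 (camera adjusted p = 0.030, adjusted p = 0.44 with an estimated correlation). GLK1 stood at 187 ± 13.7 against 349 ± 15.2 TPM and GLK2 at 8.4 ± 2.87 against 138 ± 3.22 TPM. All 6 epidermis markers fell alongside (camera adjusted p = 0.0051, adjusted p = 0.34 with an estimated correlation), PDF1 (AT2G42840) to 2.49 ± 1.41 against 135 ± 6.13 TPM. All 20 cell cycle genes fell (camera adjusted p = 2.5e-04, adjusted p = 0.46 with an estimated correlation).

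In the senescence list 19 of 22 rose and 2 fell (camera adjusted p = 2.5e-05, adjusted p = 0.30 with an estimated correlation). SAG12 (chromosome 5, 18613259 to 18614930, forward strand) stood at 205 ± 32.6 TPM in coronatine leaves and was listed at 0 in all 3 mock libraries. ORE1 reached 109 ± 14.7 against 1.4 ± 0.475 TPM, and NAP, lower than mock at 1 and 3 h, reached 94.4 ± 7.00 against 15.8 ± 3.61 TPM. Autophagy genes rose in 32 of 34 (camera adjusted p = 1.6e-09, adjusted p = 0.19 with an estimated correlation). Vacuolar and senescence proteases rose in 4 of 7 (camera adjusted p = 0.049, adjusted p = 0.41 with an estimated correlation), with RD21A (AT1G47128) at 2411 ± 103 against 289.8 ± 11.40 TPM. The protease call was not kept without coronatine 24 h replicate 2 (camera adjusted p = 0.051). The abscisic acid list rose in 9 of 11 with 1 falling (camera adjusted p = 0.0040, adjusted p = 0.22 with an estimated correlation). Salicylate genes rose in 11 and fell in 2 of 15 (camera adjusted p = 0.035, adjusted p = 0.70 with an estimated correlation). PBS3 (AT5G13320) reached 271 ± 23.2 against 4.95 ± 0.955 TPM, while PR1 (AT2G14610), the usual marker, read 133 ± 12.1 against 184 ± 36.1 TPM and did not pass.

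The jasmonate lists at 24 h held 12 of 13 JAZ genes that rose (camera adjusted p = 3.3e-05, adjusted p = 0.15 with an estimated correlation) and 10 of 10 turnover genes that did (camera adjusted p = 2.6e-05, adjusted p = 0.29 with an estimated correlation). Synthesis genes rose in 16 of 17 with 1 falling (camera adjusted p = 2.5e-05, adjusted p = 0.24 with an estimated correlation) and signalling regulators in 12 of 15 with 2 falling (camera adjusted p = 0.0042, adjusted p = 0.22 with an estimated correlation). JAZ10 (AT5G13220) stood at 918 ± 55.1 against 24.8 ± 3.23 TPM and LOX2 at 15324 ± 616 against 3114 ± 393 TPM. Defence markers divided into 8 that rose and 6 that fell (camera adjusted p = 0.28). VSP1 reached 13411 ± 1794 against 661 ± 205 TPM. PDF1.2 fell to 419 ± 227 against 10711 ± 43.9 TPM, a log2 difference of −4.82 ± 0.24 (limma adjusted p = 7.4e-16), and its activator ORA59 fell to 0.163 ± 0.0404 against 83.5 ± 3.67 TPM. Indole glucosinolate genes rose in 13 and fell in 2 of 17 (camera adjusted p = 0.0013, adjusted p = 0.36 with an estimated correlation). Aliphatic glucosinolate genes fell in 13 and rose in 2 of 16 (camera adjusted p = 0.042, adjusted p = 0.70 with an estimated correlation). MAM1 (AT5G23010), a chain-elongation enzyme, fell to 8.94 ± 6.61 against 293 ± 13.6 TPM. The anthocyanin list had 3 members that rose and 4 that fell of 16 (camera adjusted p = 0.86).

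**Figure D2:**
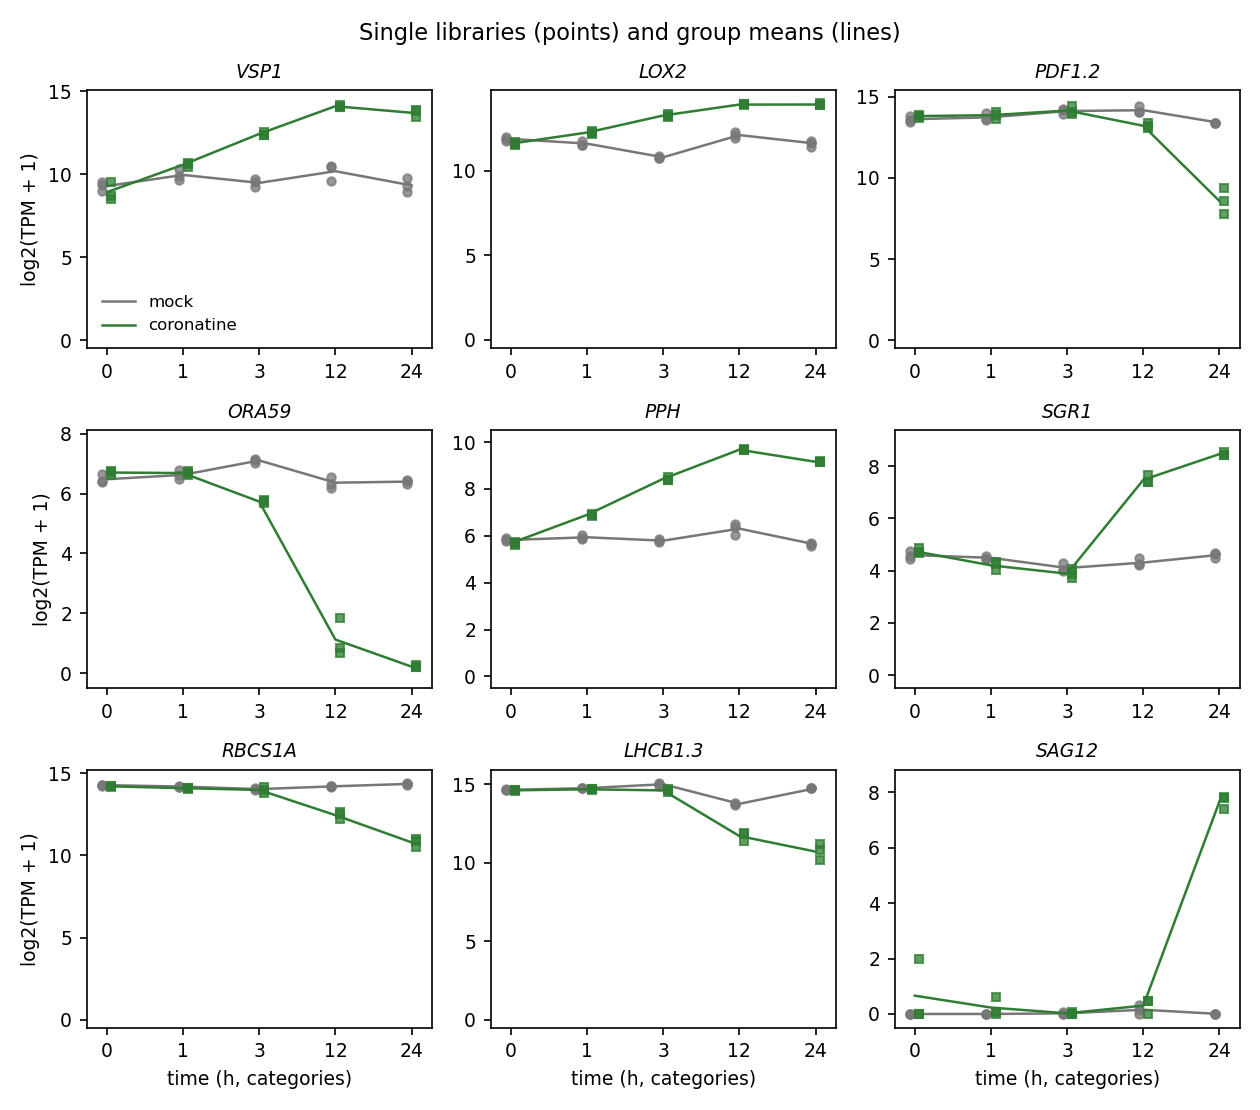
Expression of 9 genes, as log2(TPM + 1), against time in h (drawn as categories), with a point per library, 3 per group, and lines through the group means; mock is grey and coronatine green. The points of VSP1, LOX2, PPH and SGR1 lie above mock at 12 and 24 h, those of ORA59, RBCS1A and LHCB1.3 below, PDF1.2 falls to 419 TPM at 24 h, and SAG12 reaches 205 TPM in coronatine leaves at 24 h.

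Limma called 16691 genes at 24 h on TPM as deposited, 7079 higher and 9612 lower. After TMM rescaling it called 16838, 8567 higher and 8271 lower. Quantile normalization gave 8234 higher and 8082 lower, and the authors' deposited table listed 8539 higher and 8775 lower. On both TPM scalings 7079 were higher and 8271 lower.

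**Figure D3:**
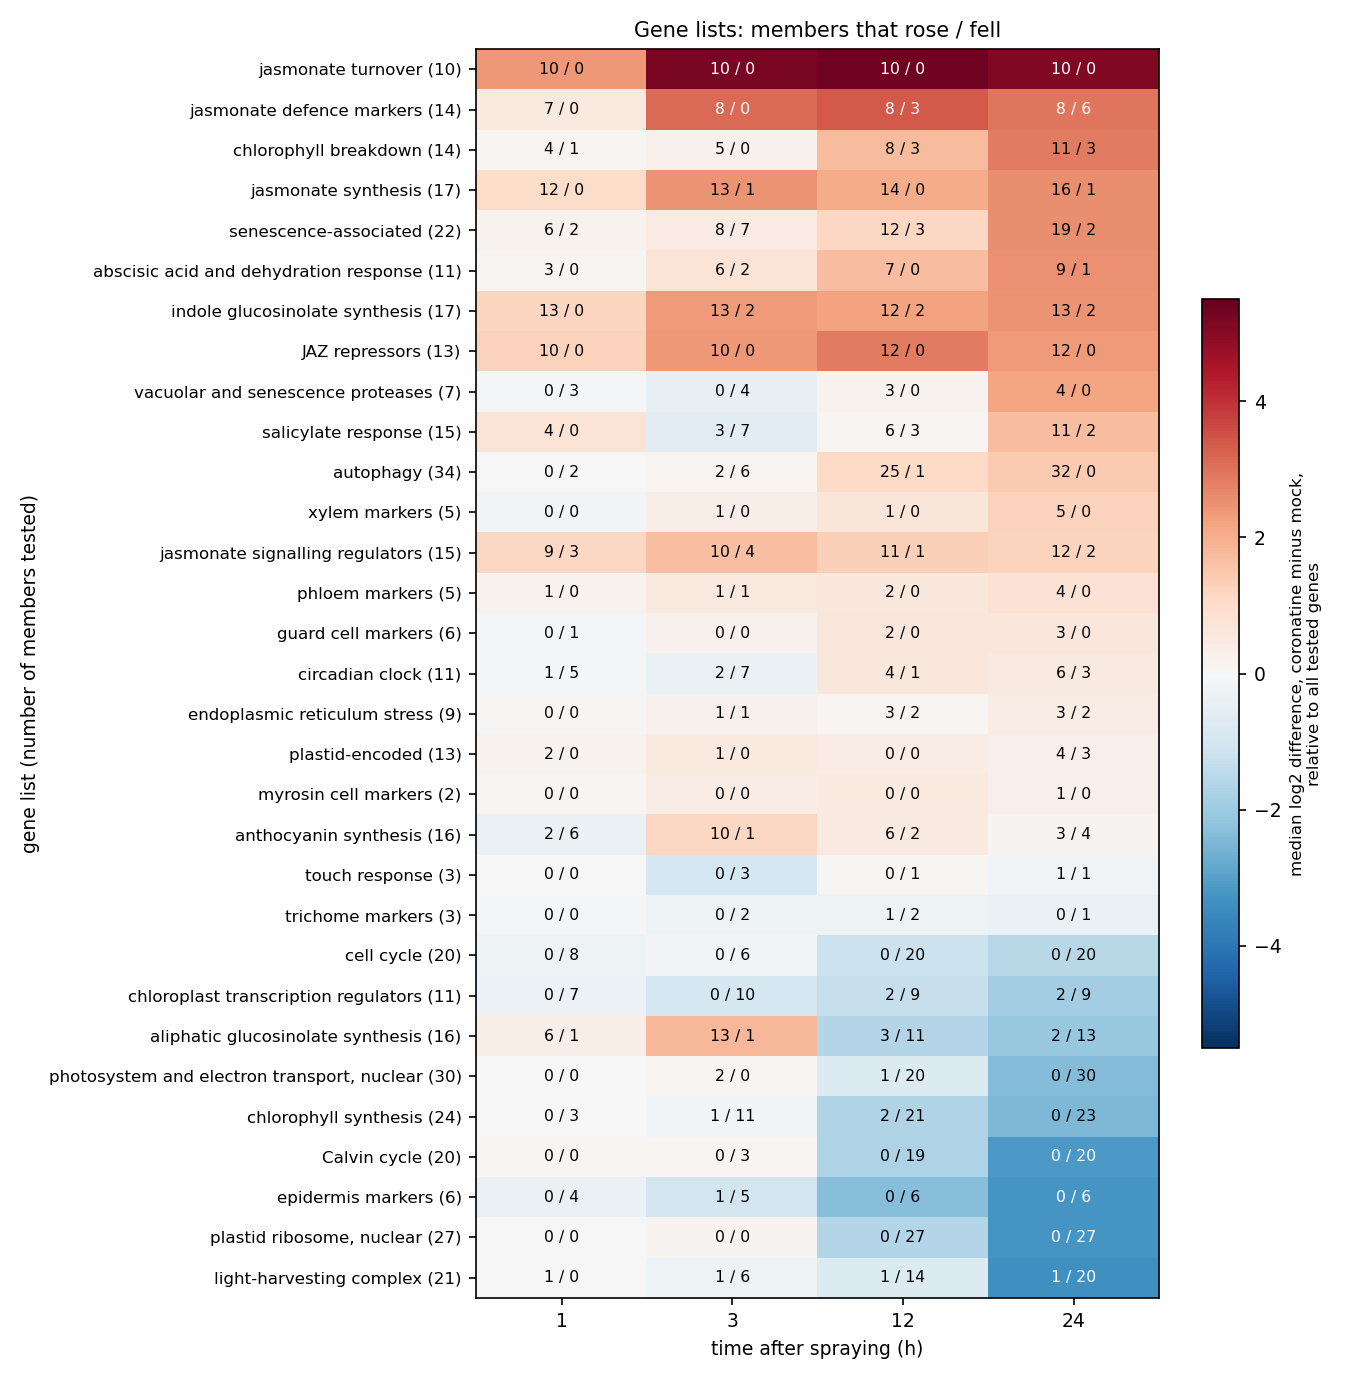
Median log2 difference (coronatine minus mock) of each gene list relative to all tested genes, as colour, at 1, 3, 12 and 24 h, with the number of members that rose and fell written in each cell and the number tested beside each list name. Jasmonate turnover had 10 risers of 10 at each of these times, and the Calvin cycle list went from 0 that fell at 1 h to 20 at 24 h.

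Whether the coronatine effect depended on time was tested directly, as the difference between coronatine minus mock at 2 times. Against 0 h, the effect on JAZ8 at 1 h was larger by 5.00 ± 0.22 log2 units (± SE), with MAPKKK21 (5.56 ± 0.43), MYB24 (5.05 ± 0.26), MAPKKK19 and RAP2.6 also among the largest. HBI1 (−2.21 ± 0.12), CDEF1 (AT4G30140), COL2, BBX14 and EPR1 (AT1G18330) were the most negative. At 3 h the leading genes were BSMT1 (7.73 ± 0.63), ILL5, CYP94B1, CYP71B37 and GSTU6, opposite ACD6 (−5.40 ± 0.64), EXPA8, GASA6, FRO6 and KCS12. At 12 h they were TPS10 (AT2G24210, 8.67 ± 0.60), GSTU6, MSRB7, PGAZAT and ILL5, opposite ACD6 (−7.18 ± 0.64), AACT1 (AT5G61160), LTL1, GER3 and FBA5. At 24 h TPS10 (AT2G24210, 10.86 ± 0.60), MSRB7, BGLU22, GH9B15 and PGAZAT led, opposite LHCB2.3 (−8.35 ± 0.20), AACT1 (AT5G61160), FBA5, RBCS2B and LHCB1.4. Between 24 h and 1 h the effect grew most in GH9B15 (9.67 ± 0.19), PGAZAT, DXPS1, BGLU22 and GLYI7 (AT1G80160). It became most negative in AACT1 (AT5G61160, −8.19 ± 0.53), LHCB2.3, RBCS2B, FBA5 and CA2.

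The limma interaction test called 6702 genes for 1 h against 0 h on TPM as deposited, 1428 higher and 5274 lower. It gave 2110 higher and 1728 lower after TMM rescaling and 1883 higher and 2446 lower after quantile normalization. For 3 h it called 14154, 2331 higher and 11823 lower, against 5886 higher and 5883 lower after TMM rescaling and 5020 higher and 6740 lower after quantile normalization. For 12 h it called 15307, 4043 higher and 11264 lower, against 7663 higher and 7368 lower after TMM rescaling and 6978 higher and 7528 lower after quantile normalization. The test called 15687 genes for 24 h against 0 h, 6463 higher and 9224 lower, against 8077 higher and 7791 lower after TMM rescaling and 7636 higher and 7504 lower after quantile normalization. For 24 h against 1 h it called 15210, 7173 higher and 8037 lower, against 7875 higher and 7538 lower after TMM rescaling and 7660 higher and 7128 lower after quantile normalization.

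Mock leaves changed over the 24 h as well, clock genes among them. These leaves were sprayed with water, so their changes from 0 h cannot be assigned to time of day apart from the spray. CCA1 (AT2G46830), a morning gene, read 143 ± 3.52 TPM at 0 h, 83.9 ± 6.50 at 1 h, 24.7 ± 2.2 at 3 h, 1.36 ± 0.207 at 12 h and 140.0 ± 7.34 at 24 h. LHY (AT1G01060) differed from 0 h by −3.79 ± 0.09 log2 units at 3 h. The evening-phased PRR5 (AT5G24470) differed from 0 h by 5.84 ± 0.09 at 3 h, and TOC1 (AT5G61380) by 2.99 ± 0.11 at 12 h. At 12 h LHCB2.3 had changed by −5.69 ± 0.14 in mock leaves, while RBCS1A read 18960.0 ± 429 TPM against 19861 ± 524 at 0 h. The mock changes of PRR5, TOC1 and LHCB2.3 were chosen after their values were seen.

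Limma called 3934 genes between mock leaves at 1 and 0 h, 2418 higher and 1516 lower, against 2121 higher and 1834 lower after TMM rescaling and 2157 higher and 2289 lower after quantile normalization. At 3 h it called 8908, 5042 higher and 3866 lower, against 4449 higher and 4307 lower after TMM rescaling and 4508 higher and 4640 lower after quantile normalization. At 12 h it called 11541, 9619 higher and 1922 lower, against 3929 higher and 4017 lower after TMM rescaling and 4498 higher and 3880 lower after quantile normalization. At 24 h, the same time of day as 0 h, it called 97, 70 higher and 27 lower, against 42 higher and 28 lower after TMM rescaling and 65 higher and 40 lower after quantile normalization. The 24 h count rested on single libraries: it was 21 without mock 24 h replicate 2, 37 without mock 0 h replicate 2 and 49 without mock 0 h replicate 3.

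Early and late responses shared genes beyond independent lists of their size. Of 1809 genes higher at 1 h on both scalings, 1547 were higher at 3 h, where independent lists would share 256 (Fisher's exact test, odds ratio 82.5, 95% confidence interval 71.4 to 95.9). Of 2942 lower at 1 h, 2380 were lower at 3 h (odds ratio 11). From 3 to 12 h, 2172 higher genes (odds ratio 23.7) and 4966 lower genes (odds ratio 8.20) were shared. From 12 to 24 h, 4306 higher (odds ratio 59.6) and 7021 lower genes (odds ratio 61.0) were. Between 1 and 24 h, 1420 higher genes (odds ratio 7.44) and 2079 lower genes (odds ratio 3.84) were shared. Another 201 went from higher to lower and 427 from lower to higher. The Pearson correlation of log2 differences across genes, which are not independent replicates, was 0.78 between 1 and 3 h, 0.74 between 3 and 12 h, 0.90 between 12 and 24 h and 0.47 between 1 and 24 h. Label numbers, those in the sample descriptions, recur across times within a treatment, and whether they mark the same plants is unknown. In 47 pairs of samples with the same treatment and label number at different times, deviations had a median correlation of −0.0074 (from −0.26 to 0.30). The times share no libraries, but the limma calls at all times share 1 estimate of the spread per gene. Fisher's exact test also treats genes as independent, so its odds ratios and intervals are descriptive.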

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

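The tests of the aliphatic glucosinolate pattern, the test of the amount per leaf, and the tests of lists and named genes between 2 later times were chosen after the results were seen.

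The coronatine effect differed from that at 0 h by the limma interaction test in 6702 genes at 1 h, 14154 at 3 h, 15307 at 12 h and 15687 at 24 h, and differed between 24 h and 1 h in 15210. Of 100 drawn regroupings within the 2 times, the real one included, 3, 1, 2, 5 and 5 gave as many genes for these differences in turn, with highest others of 6849, 14067, 15347, 15793 and 15494. Every regrouping with as many genes kept the real grouping at the later time, as 11, 8, 9, 9 and 10 of the 100 did. These shares therefore follow how many draws kept that grouping and do not decide on chance. Where the later grouping was changed, 0 regroupings gave as many genes, and the highest counts were 1, 0, 0, 0 and 1210.

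NAP was lower in coronatine leaves at 3 h and higher at 24 h, all 3 coronatine values lying beyond all 3 mock values each time, and the difference between the effects was 4.90 ± 0.31 (limma adjusted p = 2.3e-13), or 4.84 after TMM rescaling.

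The aliphatic glucosinolate list was called higher at 1 and 3 h and lower at 24 h by camera at the preset correlation. None of these calls held with an estimated correlation (camera adjusted p = 0.46, 0.24 and 0.70). The median difference between the effects was −2.57 for 24 h against 1 h (camera adjusted p = 0.0029, adjusted p = 0.55 with an estimated correlation) and −3.63 for 24 h against 3 h (camera adjusted p = 9.7e-08, adjusted p = 0.28 with an estimated correlation). After TMM rescaling, mock leaves fell between 0 and 3 h, with a median of −1.31 and 15 of 16 genes below 0. A fall of mock leaves alone is argued against by coronatine leaves themselves, whose median at 3 h lay 0.99 above 0 h after TMM rescaling (median SE 0.139, 13 of 16 genes above 0). At 3 h the TPM of the median gene was lower in coronatine leaves (−0.46), so a shift of the TPM scale could not by itself raise the list. TMM rescaling took the list median at 3 h from 1.34 to 1.90. The shift itself set that direction, so this test decides nothing further. A change of the effect with time may be biological, which was not tested apart from the calls themselves.

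The median log2 TPM difference of all genes lay at −0.54 at 12 h. It was −0.55 without the 100 most abundant genes (from −0.56 to −0.54 without any 1 library), which took 28.4% of TPM in coronatine and 27.6% in mock leaves, so that a larger share of those genes is not its source. A pseudocount draws log2 differences toward 0, so it would not by itself put the median below 0, whatever a test gave. Among the 10223 genes with a mean TPM of at least 10 the median was −0.41 (from −0.42 to −0.40), so it did not rest on low genes alone. Whether most transcripts fell in amount per leaf cannot be told apart from a change of a part of them, because TPM holds no absolute amount and the TMM-scaled median, 0.025, is near 0 by construction. Because each sample's TPM has the same total, a lower median gene means that other genes took a larger share of TPM. A change in composition of the measured RNA therefore follows from the unit, and the amount per leaf stays open.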

How the results depend on the processing

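The joint call on both scalings and the alternatives for mock leaves, for overlaps and for an estimated correlation on TMM-rescaled TPM were chosen after seeing the data. Where a value moved and no reason is given, the cause was not tested. At 0 h, limma called 1 gene with a pseudocount of 0.1, 7 with no filter and 2 with sample weights, against 0. TMM rescaling gave 6132 genes at 1 h and the authors' deposited table listed 6019, against 9733. For 1 h against 0 h, quantile normalization gave 4329 and TMM rescaling 3838, against 6702. Asking also for a log2 difference of at least 1, which can only lower a count, left 1071, 5250, 8561 and 9256 genes at 1, 3, 12 and 24 h, 1149, 5561, 8624 and 9155 for the differences from 0 h at these times, 8205 for 24 h against 1 h, and 222, 1137, 1230 and 11 for mock leaves at 1, 3, 12 and 24 h. Calls alike on both scalings, also lower by construction, numbered 4751 at 1 h, 9541 at 3 h, 3152 and 8214 for 1 and 3 h against 0 h, and 5850 in mock leaves at 12 h. Sample weights gave 381 genes in mock leaves at 24 h, against 97. With an estimated correlation camera called 1, 5, 4, 0 and 0 lists at 0, 1, 3, 12 and 24 h, against 16, 14, 13, 18 and 20, with 3, 6, 9, 7 and 6 at an unadjusted p under 0.05. On TMM-rescaled TPM with an estimated correlation it called 0 lists at each time, with 3, 6, 6, 7 and 3 at an unadjusted p under 0.05. Under TMM rescaling the nuclear photosystem list at 3 h had a relative median of 0.21 and was called higher (camera adjusted p = 0.040), as was the plastid ribosome list at 0.24 (camera adjusted p = 0.015), the reverse of most single-gene calls on TPM as deposited. Neither was called there with an estimated correlation (camera adjusted p = 0.76 and 0.69), and after quantile normalization both were called lower (camera adjusted p = 0.00028 and 0.00010, relative medians −0.54 and −0.38). RBCS1A at 3 h, at −0.05 on TPM as deposited, was 0.51 after TMM rescaling and 0.50 in the authors' deposited table. SGR1 at 3 h, at −0.22 on TPM as deposited, was 0.23 after quantile normalization, 0.31 after TMM rescaling and 0.31 in the authors' deposited table. All other counts of changed genes stayed within 1.5 times their main value under the alternatives run, and each overlap stayed above that of independent lists. Without 1 sample the counts ranged from 0 to 1 at 0 h (1 without coronatine 0 h replicate 3 or mock 0 h replicate 3), from 7605 to 9533 at 1 h, 14947 to 15254 at 3 h, 15941 to 16031 at 12 h and 16363 to 16477 at 24 h, and from 21 to 75 for mock leaves at 24 h (21 without mock 24 h replicate 2, 37 without mock 0 h replicate 2 and 49 without mock 0 h replicate 3). Of 153 pairs of named gene and time, 147 kept their direction and side of the threshold under TMM rescaling, 149 under quantile normalization and 148 without any 1 sample, as did 143 of the 149 with values in the authors' deposited table. Each other alternative changed at most 1 of them. Of the 155 pairs of list and time, 132 kept their call without any 1 sample, 16 lost it and 7 gained it. Quantile normalization kept 132, and TMM rescaling 144. The replicate numbers did not pair the samples, with correlations of same-numbered deviations from −0.25 to 0.12, of which 2 of 15 were over 0.1. With the replicate block limma called 1, 9677, 15505, 16294 and 16688 genes at 0, 1, 3, 12 and 24 h. DESeq2 and edgeR on counts were not run, because the files used here hold no counts; depth is unknown, so its limit on low genes could not be given.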

Other observations

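The tests of the daily rhythm and of a general recovery of photosynthesis transcripts were chosen after the results were seen.

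Among markers of guard cells, phloem, xylem, trichomes and myrosin cells, single members rose or fell at 24 h, and camera called none of these lists over all libraries. Guard cell markers rose in 3 of 6 and fell in 0 (camera adjusted p = 0.28), with the potassium channel KAT1 (AT5G46240) at 61.2 ± 3.03 against 5.73 ± 0.296 TPM. Phloem markers rose in 4 of 5 (camera adjusted p = 0.16), with the sucrose transporter SWEET12 (AT5G23660) at 193 ± 12.8 against 27.5 ± 0.729 TPM, and xylem markers in 5 of 5 (camera adjusted p = 0.062), with the protease XCP1 (AT4G35350) at 27.7 ± 3.49 against 9.83 ± 0.174 TPM. Without mock 24 h replicate 3 camera called the xylem list (adjusted p = 0.046). Trichome markers fell in 1 of 3 (camera adjusted p = 0.51), GL1 (AT3G27920) to 0.0833 ± 0.0850 against 1.83 ± 0.363 TPM, and myrosin cell markers rose in 1 of 2 (camera adjusted p = 0.90), TGG2 (AT5G25980) to 3949 ± 187 against 2786 ± 157 TPM. No floral marker passed the filter: 0 of 5 did, with 0.48 TPM as the highest value of any.

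Clock genes at 24 h rose in 6 and fell in 3 of 11 (camera adjusted p = 0.47). LUX (AT3G46640) stood at 56.7 ± 3.26 against 8.88 ± 0.943 TPM and CCA1 at 73.0 ± 8.53 against 140.0 ± 7.34 TPM. At 12 h the clock list was called higher (camera adjusted p = 0.046, adjusted p = 0.39 with an estimated correlation), with 4 members that rose and 1 that fell. That call was lost without coronatine 12 h replicate 1 (camera adjusted p = 0.053). Of 9 endoplasmic reticulum stress genes 3 rose and 2 fell (camera adjusted p = 0.44), with the transcription factor BZIP60 (AT1G42990) at 105 ± 2.52 against 39.9 ± 1.66 TPM. Touch genes rose in 1 and fell in 1 of 3 (camera adjusted p = 0.90), TCH3 (AT2G41100) to 554 ± 60.8 against 222 ± 21.2 TPM. Plastid-encoded genes at 24 h rose in 4 and fell in 3 of 13 (camera adjusted p = 0.88), with psbA (ATCG00020) at 28.8 ± 11.5 against 14.9 ± 3.24 TPM and atpB (ATCG00480) at 216 ± 17.2 against 477 ± 27.5 TPM, beside the nuclear photosynthesis genes, nearly all of which fell. Camera called this list lower at 0 h and higher at 1 and 3 h (adjusted p = 5.0e-04, 0.046 and 0.018). None of these calls held with an estimated correlation (camera adjusted p = 0.30, 0.55 and 0.46). By the joint rule 2 members rose at 1 h and 1 at 3 h, and 0 fell. The 3 h call was lost without coronatine 3 h replicate 2 (camera adjusted p = 0.067). The 1 h call was lost without coronatine 1 h replicate 1 (camera adjusted p = 0.11), coronatine 1 h replicate 2 (camera adjusted p = 0.080) or mock 1 h replicate 3 (camera adjusted p = 0.11). The call of psbA was lost without coronatine 24 h replicate 3 (limma adjusted p = 0.087). Whether the libraries captured plastid RNA in proportion to its amount was not tested, so these values are not read as plastid transcript levels.

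Light-harvesting genes were lower at 12 h than at 24 h in mock leaves (20 of 21 genes higher at 24 h) and in part of the coronatine leaves' genes (10 of 21, after TMM rescaling). Across the 98 genes of the 4 photosynthesis lists, the 24 h minus 12 h differences in mock and coronatine leaves had a Spearman's rho of 0.637 (permutation p = 1e-05, the smallest that 100000 permutations can give), across genes, which are not independent replicates. A daily rhythm kept in coronatine leaves may account for this, as a hypothesis. A general recovery is argued against by the 49 genes that moved by less than 0.5 in mock leaves, whose median change in coronatine leaves was −1.35 (median SE 0.0791).

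For coronatine against mock at each time there are 10 splits of the 6 samples, too few for a share under 0.05. The real split called 0 genes at 0 h, where all 10 gave as many and the highest other gave 2. At 1, 3, 12 and 24 h it called 9733, 15536, 16309 and 16691, the highest others 1, 0, 0 and 0, so 1 of the 10 gave as many each time. For mock leaves at 1, 3, 12 and 24 h it called 3934, 8908, 11541 and 97, the highest others 1, 1, 1 and 0, and 1 of the 10 gave as many each time. Camera called 16, 14, 13, 18 and 20 lists at 0, 1, 3, 12 and 24 h, the highest other splits 12, 16, 19, 18 and 19, and 1, 6, 7, 3 and 1 of the 10 gave as many. For the genes shared between times, 1 of 100 drawn regroupings, the real one, gave as many in each of the 8 overlaps. Splits other than the real one and its mirror called next to no genes at a single time, so that few shared genes follow by construction and this count does not decide on chance. The highest other regroupings shared 0 and 0 genes (higher and lower) for 1 and 3 h, 0 and 0 for 3 and 12 h, 59 and 127 for 12 and 24 h, and 1 and 0 for 1 and 24 h. The 59 and 127 come from the real split with the treatments exchanged at 1 of the times: the real split called 59 genes higher at 12 h and lower at 24 h, and 127 the other way.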
